A study of Solanum tuberosum with 4 samples.

How the data were processed

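RNA sequencing libraries of 4 potato samples were analysed, 1 each for dark leaf, red light leaf, dark microtuber peel and red light microtuber peel. Per the labels, RNA was extracted with TRIzol, libraries were made with a TruSeq RNA kit and sequenced on an Illumina HiSeq 2000. TopHat is named by the submitters' processing notes, with no version or role. The aligner settings, the counting program, the genome build and the treatment of reads that match several genes are not given in the sources used here. Per the file headers, each deposited table gives a gene identifier, a product description, a read count, an exon length and an RPKM value for 39028 genes. The authors' deposited RPKM values equal the count scaled by exon length and by the total of the counts, with a largest relative difference of 0.000497%, so the counts were used and the RPKM values served only for this check. None of the gene identifiers matched the reference table used here (0 of 39028), so no coordinates or further symbols are given.

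Read totals were 22315208 for dark leaf, 20624211 for red light leaf, 23940921 for dark tuber and 21569551 for red light tuber. In the dark tuber library 3 genes had an odd count, 0.0121% of its genes with reads, against 49.7% to 50.2% in the other libraries. Its reads were therefore taken as counted in pairs of 2, and its counting intervals used the count divided by 2. This departs from the design fixed before the data were examined, and was decided after the counts were seen. A count of 0 allows up to 3 counts, which is 0.125 CPM in dark leaf, 0.129 in red light leaf, 0.277 in dark tuber and 0.153 in red light tuber.

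Counts were scaled with TMM factors over the 4 libraries (1.07, 1.13, 0.905 and 0.910 in the order above; edgeR 4.0.16 in R 4.3.3) and expressed as CPM, the count scaled to library size. Genes with a mean of at least 1 CPM in the pair compared were measured. With 1 library per group no comparison of 2 groups has a test across samples, and no p-values are given. A model of light with tissue as a block, which would leave 1 residual degree of freedom and count differing light responses of the tissues as noise, was not run. For each gene the ratio was given an exact 95% Clopper-Pearson interval from the share of the reads of both libraries, and a gene was called at least 2-fold higher or lower where the whole interval lay beyond 2-fold. Where a library had no read, the ratio was bounded with 3 counts. PCR copies are not independent molecules, so intervals cover counting error only, and they compare libraries, not conditions. Near-identical counts in all libraries, within 1%, with the same description, were found for 22 of 15297 genes with a mean of at least 100 reads, and paralogs can share reads in ways that this check cannot show.

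Gene lists, 40 in all, were fixed before the data were examined from words in product descriptions. Each list's median of log2 ratios, with 0.5 CPM added, was set against 10000 random lists of the same size matched on mean CPM in 20 bins. A list was called apart above percentile 97.5 or below 2.5, which describes these libraries and is no test across samples. Words in descriptions also caught wrong members, such as a ribosome-recycling factor among cell cycle genes, rubisco-binding chaperonins in the Calvin cycle, chlorophyll b reductase in chlorophyll synthesis and a phosphoglycerate kinase in photorespiration. Named genes were chosen by a rule fixed beforehand. For each light comparison it takes the 6 highest and 6 lowest ratios, ranked by the interval bound nearest 1, among described genes with at least 10 CPM in a library. It also takes, from each list reported with members, the most abundant member and those of highest and lowest ratio among members with at least 10 CPM in a library, so fainter members can lie beyond them. The tissue comparisons used 5 per side and the tissue marker lists, and 10 genes with opposite directions in leaf and tuber were taken by the size of the difference.

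The method was tested on simulated counts with known answers. For the leaf light comparison (19572 genes), 95.4% of intervals held the true ratio, 1 of 19372 unchanged genes was called, and 50 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 50 changed 1.5-fold were called. For the tuber light comparison (19161 genes) the coverage was 95.9%, or 90.3% when the paired reads were taken as single ones. There, 0 of 18961 unchanged genes were called, and 49 of 50 changed 3-fold, 50 of 50 changed 4-fold and 50 of 50 changed 8-fold. The pairs were built into the simulated dark tuber counts. The lower coverage with single reads therefore says nothing on whether the real reads were paired. Of 100 unshifted lists of 30 genes, 2 in leaf and 5 in tuber stood apart, and 100 of 100 lists shifted by 0.5 did so in each. The simulated counts held counting noise only, with no other variation and no genes that move together, so these rates do not carry over to the real libraries. In real leaf light, the central 95% of random lists for the 31 jasmonate genes ran from -0.40 to 0.33.

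Alternatives fixed beforehand were DESeq2 1.42.0 size factors, library totals alone, upper-quartile factors, TMM from the pair compared, no filter and a filter of 5 CPM, a ratio without interval, an interval beyond 4-fold, thinning to the smallest library, library sizes without the 20 highest genes, pseudocounts of 0.1 and 2 CPM, unmatched random lists and members of at least 10 CPM. For the relation of leaf and tuber ratios, a mean of at least 10 CPM and Pearson's r were tried. The ones added after seeing the data were the deposited counts in the interval, the count of every library divided by 2, and lists without members caught by accident. Small RNA data were not analysed here. Further work used Python 3.11.15 with SciPy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.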

Results

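RNA was sequenced from leaves and from microtuber peel of the potato (Solanum tuberosum) cultivar Zhuangshu No.3, kept in the dark or given red light, in 4 libraries with 1 library per group. Microtubers are small tubers formed in sterile culture. The dark leaves came from plantlets 8 weeks old that spent 3 days in darkness, and the red light leaves were afterwards lit at 630 nm and 19.7 µmol per square metre and second. The microtubers grew for 8 weeks in darkness at 19 °C on 8% sucrose, and the red light group then received the same light. In both tissues, RNA taken after 12, 24 and 48 h of red light was mixed in equal amounts before the library was made. The deposited tables list reads for 39028 genes, with totals of 22315208 reads in the dark leaf library, 20624211 in the red light leaf library, 23940921 in the dark tuber library and 21569551 in the red light tuber library. Reads were found for 25517, 25775, 24816 and 24999 genes in that order. The 10 most abundant genes took 5.59% and 5.33% of the reads in the leaf libraries and 9.59% and 9.41% in the tuber libraries. There were no replicates, so each comparison is between 2 libraries and has no replicate check. Ranges in brackets are exact 95% counting intervals of the ratio, and they cover counting error only. Abundance is given as CPM, the read count scaled to library size. Gene identifiers and product descriptions are those of the files, and no chromosome positions are given.

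The first question of the series, as its title and labels state it, was how red light acts on gene expression and secondary metabolism. In leaves, genes of photosynthesis, cell division and the cell wall were higher in the red light library. The lists for darkness, starvation and dormancy and for defence lay lower, and both calls depended on the filter on low counts. Carbonic anhydrase (PGSC0003DMG400000493), which interconverts carbon dioxide and bicarbonate, was 78.3-fold higher (70.3 to 87.5), and reached 1094 CPM. A germin (PGSC0003DMG400011603), from a family of cell wall glycoproteins, was 83.7-fold higher (64.2 to 111). Early nodulin 75 (PGSC0003DMG400032534), a proline-rich protein, was 86.7-fold higher (66.6 to 115), and induced stolon tip protein (PGSC0003DMG400008444) was 76.1-fold higher (51.0 to 119). A histone H2A gene (PGSC0003DMG400024029) had a ratio of 347 from few dark reads (61.9 to 13750), and a receptor-like kinase (PGSC0003DMG400023953), with no read in the dark leaf library, was at least 108-fold higher. The genes with the strongest opposite ratio included 2 enzymes of amino acid breakdown. The E2 subunit of branched-chain alpha-keto acid dehydrogenase (PGSC0003DMG400011330) was 8.09-fold lower under red light (7.64 to 8.58), and 4-hydroxyphenylpyruvate dioxygenase (PGSC0003DMG400017707), an enzyme of tyrosine breakdown, was 7.33-fold lower (7.02 to 7.65). A calcium ion binding protein (PGSC0003DMG400002864) was 11-fold lower (8.82 to 13.8), an S-locus-specific glycoprotein (PGSC0003DMG400017331) 10.6-fold lower (8.79 to 13.0), steroleosin (PGSC0003DMG402026939), an oil body protein, 8.01-fold lower (6.50 to 9.97), and a universal stress protein (PGSC0003DMG401033888) 7.90-fold lower (6.98 to 8.96). Of 19582 genes measured, 2648 were at least 2-fold higher in the red light leaf library, 1213 at least 2-fold lower and 15721 neither, by counting intervals lying wholly beyond 2-fold.

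Photosynthesis genes were higher as groups in the red light leaf library. Among the 34 measured light-harvesting chlorophyll a/b proteins, the antenna of the photosystems, 32 were higher and 0 lower, with a median log2 ratio of 2.99 (percentile 100 among random lists matched on expression). Chlorophyll a-b binding protein 3C (PGSC0003DMG400013416) was 26.4-fold higher (20.8 to 34.1). The most abundant member, chlorophyll a-b binding protein 13 (PGSC0003DMG400008564), had a ratio of 1.98 (1.92 to 2.03), and Lhcb7 (PGSC0003DMG401009929) one of 1.09 (0.965 to 1.23). Among 38 photosystem and electron transport subunits, 25 were higher and 0 lower (median 1.51, percentile 100). The photosystem II 22 kDa protein (PGSC0003DMG400017556), needed for heat dissipation of excess light, was 17.8-fold higher (16.2 to 19.7), the photosystem I subunit PSI-D (PGSC0003DMG400011816) had a ratio of 1.66 (1.63 to 1.68), and the root-type ferredoxin-NADP reductase (PGSC0003DMG400004095) was 1.23 times as abundant in the dark library (1.06 to 1.43). In the Calvin cycle, 13 of 21 genes were higher and 1 was lower (median 1.54, percentile 100). Glyceraldehyde-3-phosphate dehydrogenase B (PGSC0003DMG400029406) was 24.9-fold higher (22.0 to 28.3), the rubisco small chain 2C (PGSC0003DMG400012666) had a ratio of 1.99 (1.97 to 2.01), and the 1 lower member, a rubisco subunit binding protein (PGSC0003DMG400010424), is a chaperonin rather than an enzyme of the cycle and was 2.25-fold lower (2.10 to 2.40), with an interval no longer wholly beyond 2-fold under library totals alone (ratio 0.468). Chlorophyll synthesis had 10 of 20 genes higher and 0 lower (median 1.17, percentile 100), with Mg-protoporphyrin IX methyltransferase (PGSC0003DMG400014243) 6.01-fold higher (5.58 to 6.48) and NADPH:protochlorophyllide oxidoreductase (PGSC0003DMG400025007), the light-dependent step, 3.80-fold higher (3.69 to 3.92). Chlorophyll b reductase (PGSC0003DMG400030219), which the list's words also take in but which acts in chlorophyll breakdown, was 1.47 times as abundant in the dark library (1.42 to 1.53). Photorespiration had 5 of 9 genes higher and 0 lower (median 1.13, percentile 99.7). Its members included the H-protein of glycine decarboxylase (PGSC0003DMG400002103), 6.07-fold higher (5.63 to 6.56), glycolate oxidase (PGSC0003DMG400021248), 1.87 times as abundant in the dark library (1.81 to 1.92), and a phosphoglycerate kinase (PGSC0003DMG400022118), an enzyme of glycolysis and the Calvin cycle, 3.60-fold higher (3.52 to 3.69). Plastid ribosomal proteins followed with 30 of 58 higher and 0 lower (median 1.12, percentile 100).

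Histones, replication and cell cycle genes had 77 of 120 members higher and 2 lower in the red light leaf library (median 1.71, percentile 100). Genes matched by words for meristem and young organ markers had 7 of 27 higher and 2 lower in the same libraries (median 0.55, percentile 99.6). Many of these are described only as receptor protein kinase CLAVATA1. Histone H3.2 (PGSC0003DMG400025246), deposited on newly copied DNA, was 64.0-fold higher (44.9 to 94.4). The replication-independent histone H3.3 (PGSC0003DMG400016151) was 1.49 times as abundant in the dark library (1.46 to 1.53), and another gene described as histone H3 (PGSC0003DMG400027845) was 3.00-fold lower under red light (2.42 to 3.74). Cell wall expansion genes had 93 of 183 members higher and 6 lower (median 1.18, percentile 100). Cellulose synthase subunit 3 (PGSC0003DMG400031800) was 71.8-fold higher (44.0 to 126), cellulose synthase subunit 6 (PGSC0003DMG400020783) had a ratio of 1.08 (1.05 to 1.11), and a xyloglucan endo-transglycosylase (PGSC0003DMG400004670), which remodels wall polymers, was 3.61-fold lower (3.24 to 4.03). In nitrate and ammonium assimilation, 12 of 38 genes were higher and 0 lower (median 0.46, percentile 99.5). Glutamine synthetase (PGSC0003DMG400004355) was 20.2-fold higher (19.0 to 21.5) at 910 CPM, and a nitrate transporter (PGSC0003DMG400029396) had a ratio of 2.33 toward the dark library with an interval that spans 2-fold (1.89 to 2.89). The list for darkness, sugar starvation and dormancy lay below random lists (median -0.55, percentile 0.2), with 8 of 31 members lower and 2 higher. Asparagine synthetase (PGSC0003DMG400004170), which stores nitrogen as asparagine and is induced in carbon-starved leaves, was the most abundant member and was 2.87-fold lower under red light (2.84 to 2.91), at 1844 against 5299 CPM. Malate synthase (PGSC0003DMG400015194), a glyoxylate cycle enzyme, had a ratio of 2.33 toward red light (1.87 to 2.91). Without a filter on low counts the median of this list was -0.20 and it no longer stood apart from random lists. The list of pathogenesis-related and defence genes also lay below random lists (median -0.18, percentile 0.38), although 22 of 171 were higher and 11 lower. That call was kept in 8 of 12 alternative settings. Oxidative stress genes had 25 of 108 higher and 8 lower (median 0.42, percentile 100), with a thioredoxin peroxidase (PGSC0003DMG400028238) 6.78-fold higher (6.38 to 7.22), catalase (PGSC0003DMG400029408) 1.11 times as abundant in the dark library (1.10 to 1.12) and catalase isozyme 3 (PGSC0003DMG400009906) 7.32-fold lower (6.38 to 8.42). Cytosolic ribosomal proteins were shifted by less than 2-fold for most members, 11 of 155 higher and 2 lower (median 0.59, percentile 100).

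For secondary metabolism in leaves, both genes described as solanidine glycosyltransferases were at least 2-fold higher under red light. Of 2 rhamnosyltransferases in the same glycoalkaloid list, whose description names no glycoalkaloid, 1 was at least 2-fold higher. The 2 SGT1 genes in the list had lower values. UDP-galactose:solanidine galactosyltransferase (PGSC0003DMG400011749) was 12.0-fold higher (8.34 to 17.8) and UDP-glucose:solanidine glucosyltransferase (PGSC0003DMG400017508) 2.99-fold higher (2.64 to 3.39). Of 2 genes described as UDP-rhamnose:rhamnosyltransferase, PGSC0003DMG400016125 was 4.81-fold higher (2.86 to 8.50) and PGSC0003DMG400016194 had a ratio of 2.98 (1.94 to 4.72). The glucosyltransferase and the rhamnosyltransferases were named after their values were seen, to give the short list in full. The list of 6 genes also holds 2 genes described only as SGT1, a name shared by the galactosyltransferase and by a co-chaperone of disease resistance proteins. They went the other way, PGSC0003DMG400028904 by 2.67-fold (2.48 to 2.87) and PGSC0003DMG400020884 by 1.73-fold (1.66 to 1.80). With them the median was 1.41 (percentile 99.6, 3 higher and 1 lower). Without them it was 1.63, with genes of at least 5 CPM it was 0.38 and no longer apart from random lists (percentile 84.0), and among the more abundant members, those with at least 10 CPM, it was -0.79 and turned direction because the SGT1 genes are among the most abundant. Flavonoid and anthocyanin genes had 31 of 69 members higher and 0 lower (median 1.13, percentile 100), led by a flavonol 4'-sulfotransferase (PGSC0003DMG400020968), 18.2-fold higher (12.9 to 26.5). A pair of leucoanthocyanidin dioxygenase genes, which act late in anthocyanin synthesis, had ratios toward the dark library of 1.66 (1.57 to 1.76, PGSC0003DMG400033567) and 2.35 (1.92 to 2.89, PGSC0003DMG400026277). Members with at least 10 CPM had a median of 0.09, which no longer stood apart.

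The core phenylpropanoid and chlorogenic acid genes had 5 of 42 members higher and 1 lower in the red light leaf library (median 0.25, percentile 94.3, within the range of random lists). An anthranilate N-hydroxycinnamoyl/benzoyltransferase (PGSC0003DMG400018934) was 15.1-fold higher (12.1 to 19.1), phenylalanine ammonia-lyase 1 (PGSC0003DMG400031457), the entry enzyme, had a ratio of 1.14 (1.11 to 1.17), and tyramine hydroxycinnamoyl transferase (PGSC0003DMG400014778) was 2.52-fold lower (2.18 to 2.92). With genes of a mean of at least 5 CPM, this median was 0.39 and stood above random lists. Lignin genes had 7 of 27 higher and 1 lower (median 0.44, percentile 97.2), just within the range of random lists. That call held in 4 of 12 alternative settings and the list stood above random lists in the others, up to percentile 99.9. Suberin, cutin and wax genes had 26 of 44 higher and 0 lower (median 1.61, percentile 100), among them a fatty acid omega-hydroxylase (PGSC0003DMG400012202), 8.89-fold higher (7.39 to 10.8), and non-specific lipid-transfer protein 1 (PGSC0003DMG400001904), 2.92-fold higher (2.78 to 3.07), while a 1-acyl-sn-glycerol-3-phosphate acyltransferase (PGSC0003DMG402016888) was 1.88 times as abundant in the dark library (1.58 to 2.25). Many members of that list are lipid-transfer proteins, which are not specific to suberin or wax. Carotenoid synthesis had 5 of 20 genes higher and 1 lower (median 0.34, percentile 96.0). Neoxanthin synthase (PGSC0003DMG401026407) was 8.62-fold higher (6.62 to 11.4), while phytoene dehydrogenase (PGSC0003DMG400009156) and carotenoid isomerase (PGSC0003DMG400028224) were 1.15 (1.09 to 1.22) and 1.46 times (1.35 to 1.59) as abundant in the dark library. The carotenoid median stood above random lists at 0.45 with genes of at least 5 CPM and at 0.54 with members of at least 10 CPM. In the plastid isoprenoid pathway 0 of 11 genes were higher or lower (median 0.38, percentile 91.5). Mevalonate and sterol synthesis had 6 of 33 genes higher and 2 lower (median 0.13, percentile 87.2). Its sterol delta-7 reductase DWF5 (PGSC0003DMG400005931) was 6.34-fold higher (5.13 to 7.92), squalene monooxygenase (PGSC0003DMG400004923) was 1.57 times as abundant in the dark library (1.52 to 1.61), and a sterol C-methyltransferase (PGSC0003DMG400006855), which leads to plant sterols, was 2.92-fold lower (2.83 to 3.02).

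To ask the same of tubers, the red light microtuber library was compared with the dark one. Light-harvesting genes were low in dark peel, with a median of 0.969 CPM, and abundant under red light, with 212 CPM. The dark medians of the other photosynthesis lists were 2.95 CPM for the Calvin cycle, 3.97 for photosystem subunits, 19.8 for chlorophyll synthesis and 47.1 for photorespiration. Chlorophyll a-b binding protein 3C (PGSC0003DMG400013460) stood at 1717 CPM against 2.40, a 715-fold difference (488 to 1095). A further 3C gene (PGSC0003DMG400013411) was 885-fold higher (379 to 2725) and another chlorophyll a/b binding protein (PGSC0003DMG400019508) 554-fold higher (346 to 951). Fructose-bisphosphate aldolase (PGSC0003DMG400003123), of glycolysis and the Calvin cycle, was 678-fold higher (417 to 1186), a class I chitinase (PGSC0003DMG400010283), a defence protein, 1065-fold higher (416 to 3909), and EARLY flowering 4 (PGSC0003DMG400001221), a clock protein with no read in the dark tuber library, at least 448-fold higher. The 6 genes with the strongest opposite ratio included 2 zinc finger proteins and an AP2/ERF factor. A Cys2-His2 zinc finger protein (PGSC0003DMG400034673) was 150-fold lower under red light (50.7 to 731), a C2H2 zinc finger protein (PGSC0003DMG400002383) 49.6-fold lower (27.3 to 100), and an AP2/ERF transcription factor (PGSC0003DMG400002899) 32.1-fold lower (27.2 to 38.2), at 7.59 against 244 CPM. An autoinhibited calcium ATPase (PGSC0003DMG400043830), a calcium pump, was 51.5-fold lower (21.5 to 161), a protein phosphatase 2c (PGSC0003DMG400027174) 22.8-fold lower (20.3 to 25.6), and abscisic acid 8'-hydroxylase CYP707A1 (PGSC0003DMG402018475), which breaks down abscisic acid, 23.3-fold lower (20.0 to 27.5). Of 19141 genes measured, 1691 were at least 2-fold higher in the red light tuber library, 867 lower and 16583 neither. Under upper-quartile scaling, which shifted the median of all genes by -0.18, the counts were 1334 higher and 1195 lower, so that 52.7% rather than 66.1% of these genes were higher under red light.

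Light-harvesting genes of the tuber libraries had 33 of 34 members higher and 0 lower under red light (median log2 ratio 6.61, percentile 100). Their median was 6.65 with genes at 0 placed at their lower bound. Among members with at least 10 CPM in a library, the one of lowest ratio was chlorophyll a-b binding protein 8 (PGSC0003DMG400007787). It was 2.36-fold higher (2.03 to 2.76), or 2.32-fold with an interval that reached below 2-fold under DESeq2 size factors. Photosystem and electron transport subunits had 30 of 34 higher and 0 lower (median 5.32, percentile 100), with a photosystem I reaction center subunit (PGSC0003DMG400005805) 337-fold higher (183 to 703), oxygen-evolving enhancer protein 1 (PGSC0003DMG400010035), part of the water-splitting complex, 93.8-fold higher (80.4 to 110), and the root-type ferredoxin-NADP reductase (PGSC0003DMG400004095) 1.32 times as abundant in the dark library (1.16 to 1.52). Calvin cycle genes had 18 of 21 higher and 1 lower (median 4.36, percentile 100). The rubisco small chain 1 (PGSC0003DMG400019584) was 462-fold higher (311 to 722), and the chaperonins in this list had ratios of 1.97 toward red light (1.91 to 2.04, PGSC0003DMG400001148) and 2.30 toward darkness (2.15 to 2.47, PGSC0003DMG400010424). Chlorophyll synthesis had 17 of 21 genes higher and 0 lower (median 2.14, percentile 100). A pair of protochlorophyllide oxidoreductase genes were 42.2-fold (36.3 to 49.4, PGSC0003DMG400025007) and 25.2-fold higher (22.4 to 28.5, PGSC0003DMG400015356), while a glutamyl-tRNA reductase (PGSC0003DMG400003105), which starts the pathway, was 1.81 times as abundant in the dark library (1.60 to 2.05). Photorespiration had 6 of 9 higher and 0 lower (median 2.45, percentile 100), with hydroxypyruvate reductase (PGSC0003DMG400006186) 171-fold higher (93.1 to 358), phosphoglycerate kinase (PGSC0003DMG400022119) 2.47-fold higher (2.38 to 2.55), and glycolate oxidase (PGSC0003DMG400021248) at a ratio of 1.07 toward darkness (1.02 to 1.12). Plastid ribosomal proteins had 31 of 58 higher and 1 lower (median 1.48, percentile 100). Light-harvesting genes took 0.0144% of the reads in dark peel and 1.08% under red light, against 0.229% and 1.16% in leaves. Photoreceptor and light signalling genes as a list did not stand apart (median -0.07, percentile 23.7, 7 of 34 higher and 2 lower), although early light inducible protein (PGSC0003DMG400006442), which binds pigments under light stress, was 175-fold higher (130 to 242) and phytochrome B2 (PGSC0003DMG400027211), a red light receptor, was 2.66-fold lower (2.30 to 3.08).

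Genes of secondary metabolism in tuber peel were higher under red light at several steps. In the glycoalkaloid list, the solanidine galactosyltransferase (PGSC0003DMG400011749) was 5.15-fold higher (4.44 to 6.01), at 91.3 against 17.7 CPM, and the solanidine glucosyltransferase (PGSC0003DMG400017508) had a ratio of 1.99 (1.82 to 2.17). The SGT1 genes had ratios of 3.24 toward red light (2.34 to 4.56, PGSC0003DMG400028904) and 1.27 toward darkness (1.21 to 1.33, PGSC0003DMG400020884), and the remaining rhamnosyltransferase one of 0.478 (0.209 to 1.08). The median over 5 genes was 0.99 (percentile 98.5, 2 higher and 0 lower). It stood within random lists without the SGT1 genes (percentile 96.8) and was 0.02 without a filter on low counts, so the list as a whole is not firmly apart. Mevalonate and sterol synthesis, which supplies the sterol skeleton of these compounds, had 8 of 33 genes higher and 1 lower (median 0.60, percentile 100). DWF5 (PGSC0003DMG400005931) was 7.05-fold higher (6.30 to 7.90), obtusifoliol 14alpha-demethylase (PGSC0003DMG400016402) had a ratio of 2.07 (1.98 to 2.16), and a sterol desaturase (PGSC0003DMG402023841) had a ratio of 2.29 toward darkness (1.84 to 2.86). The core phenylpropanoid genes had 8 of 39 higher and 0 lower (median 0.63, percentile 100). A phenylalanine ammonia-lyase gene (PGSC0003DMG402021549) was 4.17-fold higher (4.08 to 4.25) and reached 4050 CPM, caffeoyl-CoA O-methyltransferase (PGSC0003DMG400006448) was 12.1-fold higher (10.9 to 13.5), and phenylalanine ammonia-lyase 1 (PGSC0003DMG400031457) had a ratio of 1.65 toward darkness (1.56 to 1.74). Flavonoid genes had 23 of 80 higher and 0 lower (median 0.29, percentile 99.2), among them chalcone synthase 2 (PGSC0003DMG400019110), 16.3-fold higher (14.2 to 18.6), and chalcone synthase 1B (PGSC0003DMG400029620), 112-fold higher (60.9 to 235), both the first committed step, while a flavonol synthase/flavanone 3-hydroxylase (PGSC0003DMG400003097) had a ratio of 2.02 toward darkness (1.61 to 2.54).

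Carotenoid synthesis in tubers had 5 of 21 genes higher and 0 lower (median 0.46, percentile 98.6). Phytoene synthase 1 (PGSC0003DMG400024063), which opens the pathway, was 63.1-fold higher (28.8 to 173), while beta-carotene hydroxylase (PGSC0003DMG400010169) and a neoxanthin synthase (PGSC0003DMG400024184) were 1.19 (1.12 to 1.26) and 1.61 times (1.30 to 2.00) as abundant in the dark library. The plastid isoprenoid pathway had 3 of 12 genes higher and 0 lower (median 0.88, percentile 99.8), with methylerythritol cyclodiphosphate synthase (PGSC0003DMG400012185) 3.13-fold higher (2.64 to 3.75), isopentenyl diphosphate isomerase (PGSC0003DMG400007268) at a ratio of 2.15 (1.99 to 2.33) and a tRNA-modifying isopentenyl enzyme (PGSC0003DMG400026541), not part of the pathway, at 1.29 toward darkness (1.03 to 1.61). Lignin genes had 7 of 32 higher and 1 lower (median 0.46, percentile 99.6). A cinnamoyl-CoA reductase (PGSC0003DMG400010092) with no dark read was at least 69.2-fold higher, a cinnamyl alcohol dehydrogenase (PGSC0003DMG401025767) had a ratio of 1.42 (1.34 to 1.49), and another cinnamoyl-CoA reductase (PGSC0003DMG400005197) had a ratio of 1.49 toward darkness (1.30 to 1.71). Starch genes lay above random lists with few members past 2-fold, 3 of 35 higher and 2 lower (median 0.36, percentile 99.2). ADP-glucose pyrophosphorylase (PGSC0003DMG400009026), listed as glucose-1-phosphate adenylyltransferase, was 25-fold higher (13.5 to 52.5), whereas granule-bound starch synthase 1 (PGSC0003DMG400012111) was 2.29-fold lower (2.24 to 2.35) and the R1 protein (PGSC0003DMG400007677), which phosphorylates starch, 2.22-fold lower (2.18 to 2.27). Protease inhibitors, abundant defence and storage proteins of tubers, had 14 of 51 higher and 4 lower (median 0.66, percentile 100) and took 5.88% of the reads under red light against 3.53% in the dark. Serine protease inhibitor 7 (PGSC0003DMG400010128) reached 18082 CPM at a ratio of 1.95 (1.94 to 1.96), the Kunitz inhibitor KPI-D12 (PGSC0003DMG400027054) had a ratio of 661 from few dark reads (118 to 26138), and CEVI57 (PGSC0003DMG400015289) was 3.80-fold lower (2.95 to 4.94). Suberin, cutin and wax genes lay above random lists by their median (0.35, percentile 99.6), although 3 of 53 were higher and 6 lower. The member with the highest mean, and those of highest and lowest ratio among members with at least 10 CPM, were all described as non-specific lipid-transfer proteins. Their ratios were 1.35 (1.31 to 1.39, PGSC0003DMG400031127) and 4.78 toward red light (3.2 to 7.41, PGSC0003DMG400032249) and 8.93 toward darkness (5.96 to 13.8, PGSC0003DMG400002471). Cell cycle genes had 12 of 111 higher and 0 lower (median 0.59, percentile 100), fewer than in leaves, a difference that was not tested. Among members with at least 10 CPM, the one of highest ratio was a ribosome-recycling factor (PGSC0003DMG400019363), which acts in plastid translation and was 6.05-fold higher (4.68 to 7.94). Histone H3.3 (PGSC0003DMG400016151) had a ratio of 1.24 (1.19 to 1.29), and cyclin H (PGSC0003DMG400009473) had a ratio of 1.52 toward darkness (1.34 to 1.73).

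**Figure D1:**
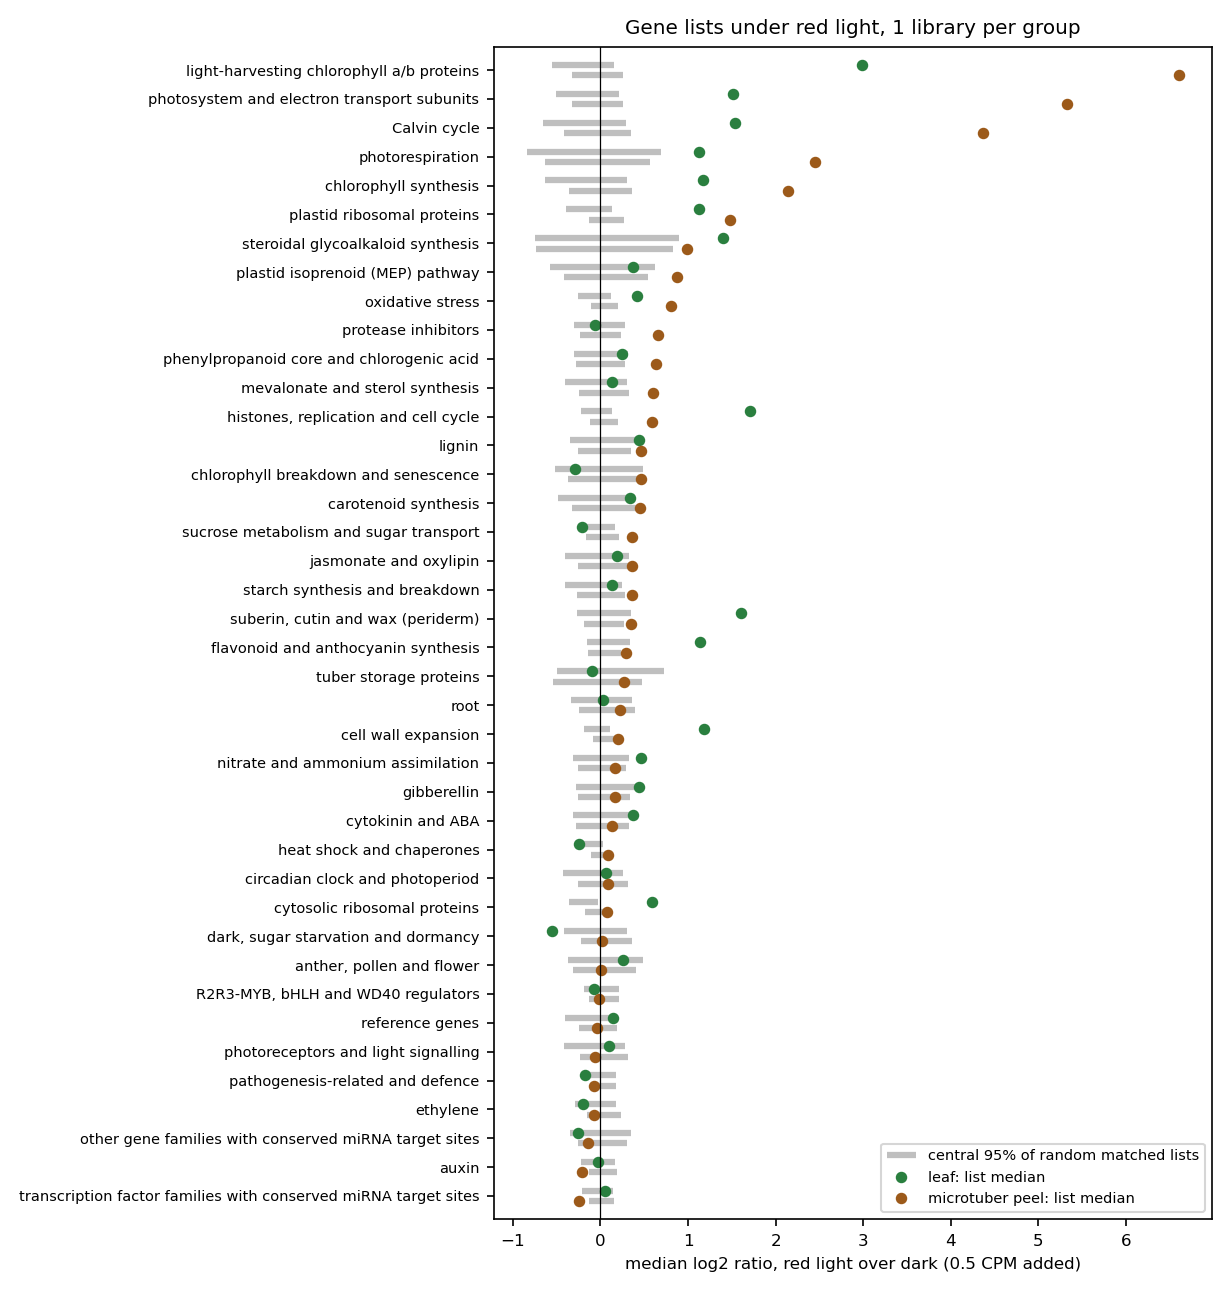
Median log2 ratio of red light over dark for 40 gene lists in leaf (green) and microtuber peel (brown), with grey bars for the central 95% of random lists matched on expression. The light-harvesting list has the highest median in both tissues, 2.99 in leaf and 6.61 in tuber.

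The study's title joins these libraries with small RNA data, which are not analysed here. Genes whose descriptions matched words for families with conserved microRNA target sites were therefore examined as a list. The words do not show that a gene has such a site, and they also caught t-complex proteins, which are chaperonins. Among 130 genes matched by words for such transcription factor families in tubers, 15 were lower under red light and 4 higher. Their median of -0.25 lay below random lists (percentile 0.01), and it was -0.23 (percentile 0.07) without members caught by accident. The AP2/ERF factor named above (PGSC0003DMG400002899), matched by the word AP2, is the member of lowest ratio among those with at least 10 CPM in a library. The GAMYB-binding protein (PGSC0003DMG400000364), by its description a partner of GAMYB and not GAMYB itself, had a ratio of 1.96 toward darkness (1.92 to 2.00). A CCAAT-binding subunit (PGSC0003DMG400022172) was 4.14-fold higher under red light (3.02 to 5.81). In leaves the same list was within random lists (median 0.06, percentile 85.3, 7 of 134 higher and 7 lower), but just above them with members of at least 10 CPM (percentile 97.7). Other families with such sites were within random lists in leaves (median -0.26, percentile 7.33, 5 of 35 higher and 2 lower) and in tubers (median -0.14, percentile 14.1, 2 of 36 higher and 2 lower), although the leaf median was -0.50 and below random lists with genes of at least 5 CPM. ARGONAUTE 1 (PGSC0003DMG400026963), which carries microRNAs, had ratios toward darkness of 1.44 in leaves (1.40 to 1.48) and 1.73 in tubers (1.67 to 1.78). Among members with at least 10 CPM, those of highest ratio were laccases, 6.51-fold higher in leaves (4.72 to 9.16, PGSC0003DMG400003512) and 23.4-fold higher in tubers (10.6 to 64.3, PGSC0003DMG400021966). Those of lowest ratio among the same members were further argonaute genes, 2.27-fold lower in leaves (2.19 to 2.35, PGSC0003DMG400021213) and 2.57-fold lower in tubers (2.32 to 2.85, PGSC0003DMG402031045). Common reference genes were not all steady. In leaves the list had 13 of 62 members higher and 2 lower (median 0.14, percentile 97.8, a call kept in 6 of 12 alternative settings, with percentiles down to 88.8), with an alpha-tubulin (PGSC0003DMG400001320) 24.4-fold higher (21.4 to 27.9), an elongation factor 1-alpha (PGSC0003DMG400019677) 6.42-fold lower (6.21 to 6.64) and polyubiquitin (PGSC0003DMG400003984) at a ratio of 1.86 toward darkness (1.84 to 1.88). In tubers 3 of 63 were higher and 5 lower (median -0.03, percentile 50.7), with actin-97 (PGSC0003DMG400027746) 3.16-fold higher (2.97 to 3.37) and the same polyubiquitin 4.03-fold lower (3.99 to 4.07).

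Light ratios of leaves and tubers were then set side by side. Among 17785 genes measured in both, 745 were at least 2-fold higher under red light in both tissues, against 192 for independent lists, and 97 were lower in both, against 46.8. Another 105 were higher in leaves and lower in tubers (95.3 for independent lists) and 63 lower in leaves and higher in tubers (94.1). The numbers for independent lists take every measured gene as equally likely to be called. Genes with many reads have narrower intervals and are called more easily in both tissues, which those numbers leave out. The leaf and tuber comparisons share no library. Across 20091 genes the Spearman correlation of the log2 ratios was 0.317, and 0.309 without the photosynthesis and chlorophyll lists, genes not being independent replicates. The AP2/ERF factor (PGSC0003DMG400002899) was 5.11-fold higher in red light leaves (4.76 to 5.49) and 32.1-fold lower in red light tubers (27.2 to 38.2). A glycine-rich cell wall structural protein (PGSC0003DMG400028955) was 38.8-fold higher in leaves (28.3 to 54.9) and at least 54.4-fold lower in tubers. A peroxidase (PGSC0003DMG400005273) was 32.0-fold higher in leaves (20.5 to 52.7) and 11.1-fold lower in tubers (7.18 to 17.9), induced stolon tip protein (PGSC0003DMG400008444) 7.68-fold lower in tubers (4.73 to 13.0), and a zinc finger protein (PGSC0003DMG401014997) 29.9-fold higher in leaves (20.3 to 46.1) and 27.2-fold lower in tubers (6.90 to 235). In the other direction, the S-locus-specific glycoprotein (PGSC0003DMG400017331) was 10.6-fold lower in leaves and 203-fold higher in tubers (127 to 349). A Kunitz-type protease inhibitor (PGSC0003DMG400015267) was 3.05-fold lower in leaves (2.68 to 3.48) and 24.3-fold higher in tubers (19.0 to 31.5), and the wound-inducible antifungal protein CBP20 (PGSC0003DMG400019437) 2.39-fold lower (2.25 to 2.54) and 15.9-fold higher (14.3 to 17.7). Serine-pyruvate aminotransferase (PGSC0003DMG400004652) was 2.27-fold lower in leaves (2.22 to 2.32) and 25.9-fold higher in tubers (21.6 to 31.3), and the dehydrin Dhn1 (PGSC0003DMG400003531), a protein of drying and cold stress, 3.50-fold lower (3.05 to 4.04) and 13.9-fold higher (9.40 to 21.4). These differences between tissues were not tested.

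**Figure D2:**
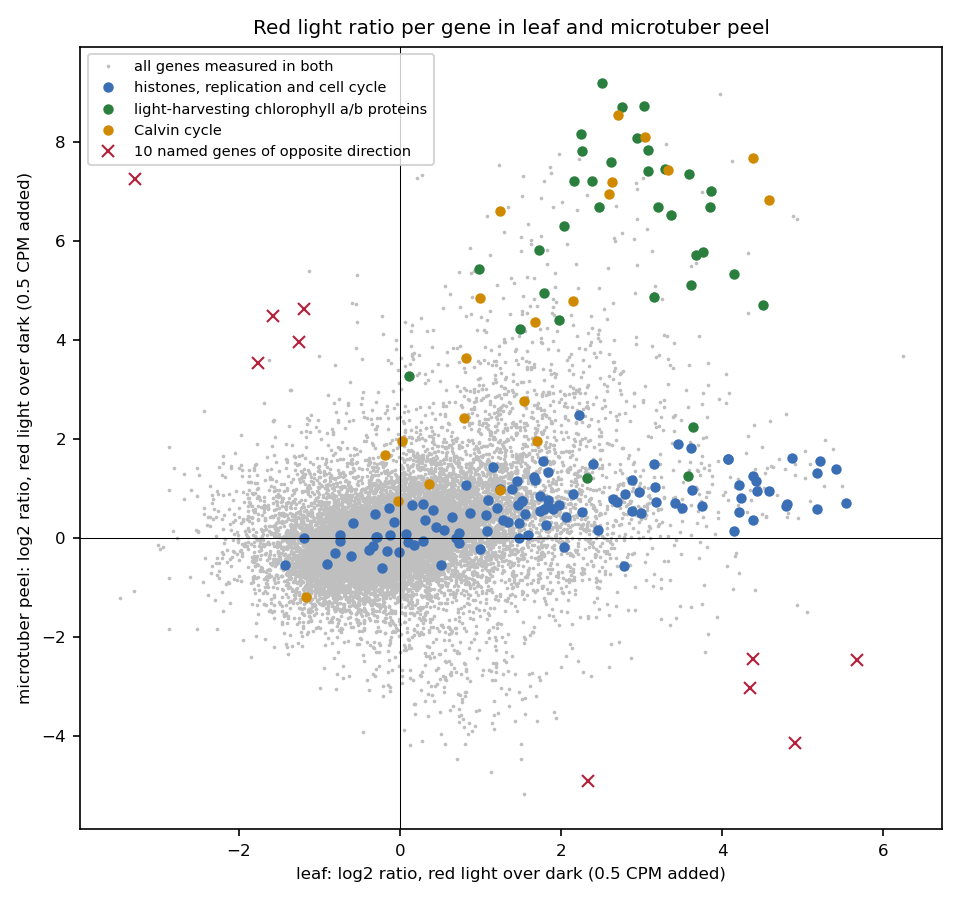
Log2 ratio of red light over dark (0.5 CPM added) per gene in leaf, on the horizontal axis, and in microtuber peel, on the vertical axis, with 3 gene lists in colour and 10 named genes of opposite direction as crosses. Across 20091 genes with a mean of at least 1 CPM over all libraries the Spearman correlation was 0.317, while the plot shows the genes measured in both comparisons, in which light-harvesting genes lie highest in tuber and cell cycle genes spread along the leaf axis.

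**Figure D3:**
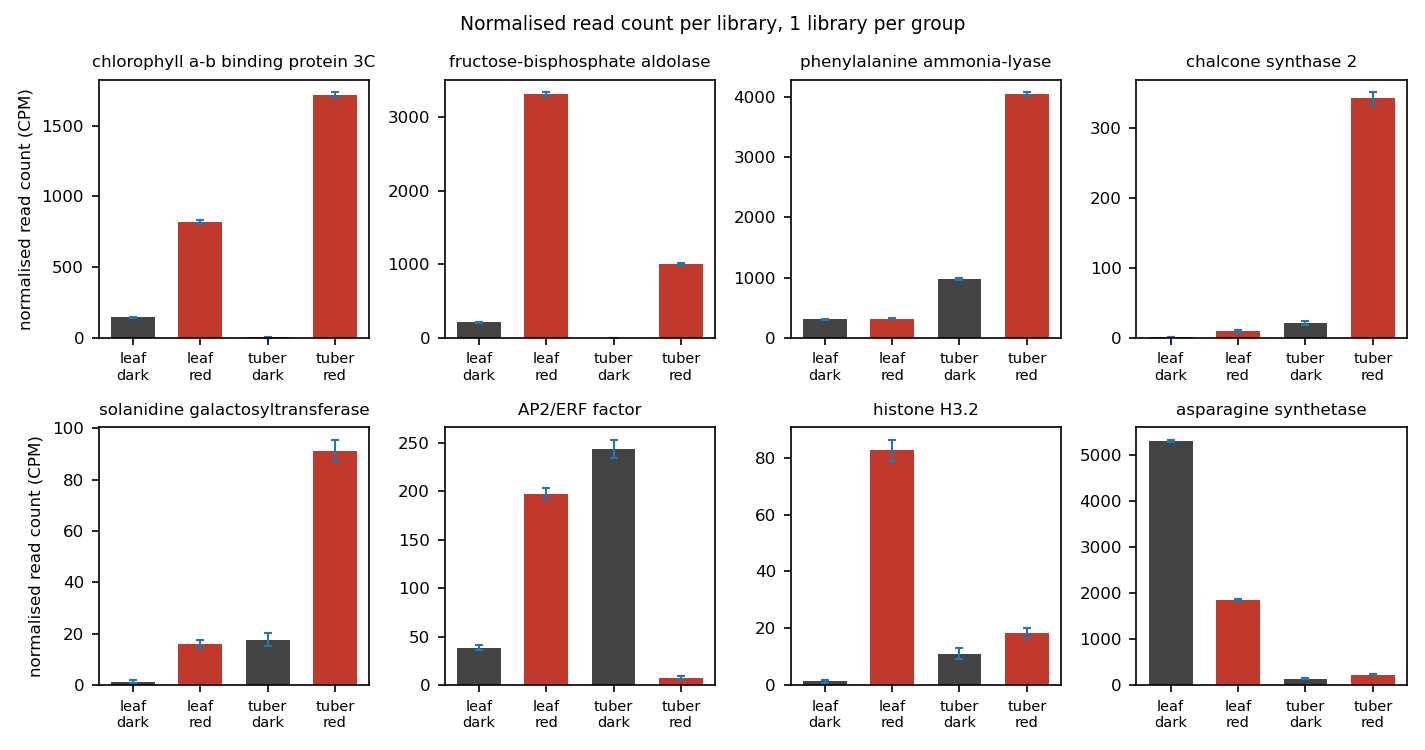
Normalised read count (CPM) of 8 named genes in the 4 libraries, with dark bars for darkness, red bars for red light and blue lines for exact 95% Poisson intervals of the count. Chlorophyll a-b binding protein 3C reaches 1717 CPM in the red light tuber library, and phenylalanine ammonia-lyase 4050 CPM.

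Without red light, leaf and tuber differed in photosynthesis, storage and barrier genes. In the dark leaf library the rubisco small chain 2C (PGSC0003DMG400012666) was 422-fold higher than in the dark tuber library (334 to 542), and acetylornithine deacetylase (PGSC0003DMG400017513), of arginine synthesis, had a ratio of 1340 from few tuber reads (240 to 52931). A group of 3 HyPRP genes, hybrid proline-rich proteins, had nearly the same counts (PGSC0003DMG400028058, PGSC0003DMG400028059 and PGSC0003DMG400028060), so their reads may be shared and the common ratio of about 993 (275 to 8206) is uncertain for each gene. In the dark tuber library patatin-05 (PGSC0003DMG400008749), a storage protein, was 1331-fold higher (988 to 1840), and patatin-2-Kuras 4 (PGSC0003DMG400014104) 986-fold higher (756 to 1313). A Kunitz-type tuber invertase inhibitor (PGSC0003DMG400010146) was 1093-fold higher there (891 to 1356), the antimicrobial Sn-1 protein (PGSC0003DMG400030255) 1176-fold higher (824 to 1744) and cysteine protease inhibitor 9 (PGSC0003DMG400010145) 932-fold higher (729 to 1210). Of 19632 genes, 3298 were at least 2-fold higher in dark leaves and 2767 in dark tubers. With library totals alone, which shifted the median of all genes by 0.24, the counts were 4066 and 2224, and 64.6% rather than 54.4% were higher in leaves. Upper-quartile scaling shifted the median by -0.18 and turned the majority, with 2839 higher in dark leaves and 3379 in dark tubers (45.7% in leaves), and leaving the 20 highest genes out of the library size shifted it by 0.11.

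Photosystem subunits were higher in dark leaves than in dark tubers for 34 of 38 genes and lower for 1 (median 4.06, percentile 100), light-harvesting proteins for 31 of 33 and lower for 0 (median 3.53, percentile 100) and Calvin cycle genes for 16 of 22 and lower for 1 (median 3.99, percentile 100). Plastocyanin (PGSC0003DMG400041620), an electron carrier, was 172-fold higher in leaves (116 to 269), and a photosystem II 10 kDa gene (PGSC0003DMG400022241) 16.7-fold higher (15.6 to 17.9), while another gene of that description (PGSC0003DMG400002312) was 19.8-fold higher in tubers (15.3 to 26.0). Suberin, cutin and wax genes were higher in tubers for 35 of 53 and higher in leaves for 6 (median -2.36, percentile 0), with a non-specific lipid-transfer protein (PGSC0003DMG400031127) 343-fold higher in tubers (250 to 486) and cutin deficient 2 (PGSC0003DMG400027770) 5.39-fold higher in leaves (4.70 to 6.20). Flavonoid genes were higher in tubers for 45 of 76 and in leaves for 10 (median -1.59, percentile 0), and lignin genes for 15 of 29 and 3 (median -1.21, percentile 0). Tuber storage proteins were higher in tubers for 8 of 13 and in leaves for 3 (median -2.20, percentile 0), among the latter patatin 3 (PGSC0003DMG400010022), 81.5-fold higher in leaves (57.7 to 119); without a filter on low counts their median was -0.44, within random lists. Protease inhibitors were higher in tubers for 21 of 50 and in leaves for 16 (median -0.62, percentile 0.1), with serine protease inhibitor 7 (PGSC0003DMG400010128) 674-fold higher in tubers (605 to 753) and a Kunitz-type inhibitor (PGSC0003DMG400009514) higher in leaves (56.4-fold to 336-fold). Without a filter on low counts the median of protease inhibitors was -0.24, no longer apart. The list for darkness and starvation was higher in dark leaves for 13 of 31 and in tubers for 2 (median 0.90, percentile 99.9).

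Under red light the photosynthesis gap between the tissues was smaller. Light-harvesting genes were higher in red light leaves for 9 of 34 and in red light tubers for 5 (median 0.44, percentile 100), photosystem subunits for 13 of 38 and 2 (median 0.79, percentile 100) and Calvin cycle genes for 12 of 21 and 2 (median 1.41, percentile 100). Chlorophyll a-b binding protein 3C (PGSC0003DMG400013460) was 2.09-fold higher in the tuber library (2.06 to 2.13), no longer past 2-fold under library totals alone (0.593 times its tuber level in leaves), a chlorophyll a/b binding protein (PGSC0003DMG400008301) 3.31-fold higher there (3.21 to 3.41) and another (PGSC0003DMG400002901) 33.6-fold higher in the leaf library (25 to 46.2), and rubisco small chain 2C (PGSC0003DMG400012666) 27.0-fold higher in leaves (26.1 to 27.9). Genes with the widest leaf excess were a germin (PGSC0003DMG400014027) at a ratio of 4051 (727 to 160034), cysteine proteinase 3 (PGSC0003DMG400027888) at 2609 (722 to 21546) and the HyPRP set (PGSC0003DMG400028060), at least 791-fold higher. Those with the widest tuber excess were the Kunitz-type tuber invertase inhibitor (PGSC0003DMG400010146), 11966-fold higher (7368 to 20934), patatin-2-Kuras 4 (PGSC0003DMG400014104), 8674-fold higher (4569 to 18970), serine protease inhibitor 7 (PGSC0003DMG400010128), 2522-fold higher (2167 to 2953), a Kunitz-type proteinase inhibitor (PGSC0003DMG400009512), 2427-fold higher (2061 to 2878), and cysteine protease inhibitor 9 (PGSC0003DMG400010145), 2828-fold higher (1944 to 4292). Protease inhibitors as a list were higher in tubers for 29 of 58 and in leaves for 14 (median -1.21, percentile 0), flavonoid genes for 44 of 84 and 12 (median -1.45, percentile 0), lignin genes for 18 of 33 and 7 (median -1.79, percentile 0) and starch genes for 14 of 36 and 4 (median -0.87, percentile 0.01). Storage proteins were higher in tubers for 7 of 14 and in leaves for 4 (median -1.14, percentile 0.160), but their median was 0.29 with library totals alone and -0.34 without a filter, neither apart from random lists. Cell cycle genes were higher in leaves for 55 of 120 and in tubers for 2 (median 1.02, percentile 100). Of 20013 genes, 3659 were higher in leaves and 2767 in tubers. With library totals alone, which shifted the median of all genes by 0.30, the counts were 4594 and 2029, and 69.4% rather than 56.9% were higher in leaves; leaving the 20 highest genes out of the library size shifted it by 0.18.

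Lists for tissues that were not sampled gave a check on the background. With the main settings they stayed within random lists in both light comparisons, but not always in the tissue comparisons. Standing apart between tissues thus does not by itself show a trait of leaf or tuber. Root genes, mostly nodulin-like descriptions, had medians of 0.03 in the leaf light comparison (percentile 62.3) and 0.22 in the tuber one (percentile 83.5), and were higher in leaves than in tubers both in darkness (median 0.64, percentile 99.1) and under red light (median 0.75, percentile 99.8). Both calls ended without a filter on low counts, at medians of 0.27 and 0.23, and the red light one also with members of at least 10 CPM, at 0.35. Without the filter the list stood above random lists in the tuber light comparison, at 0.27. Anther, pollen and flower genes had medians of 0.26 (percentile 86.0) and 0.01 (percentile 45.7) in the light comparisons. They stood below random lists for dark leaf against dark tuber (median -0.55, percentile 1.66), but their median was 0.74 with genes of at least 5 CPM, within random lists. The list was within them for red light leaf against red light tuber (median 0.44, percentile 93.7). Many of their members are cell wall allergens and extensins that leaves and peel also express. The gene lists stood above random lists in 16 of 40 cases in leaves and 21 of 40 in tubers under red light, and below them in 2 cases each.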

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

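In this part the test on the clock list was chosen after the result was seen, and the tests on wounding, as WRKY and calmodulin genes, and gene length before; the other wound-associated values were added after. Genes stand here because their red light ratio went in opposite directions in leaf and tuber, each past 2-fold in its own pair of libraries; the differences between tissues were not tested, since each rests on 1 library per group. The log2 ratio in leaf minus that in tuber was 9.04 for the glycine-rich cell wall structural protein, 8.15 for the induced stolon tip protein, 7.38 for the peroxidase, 7.25 for the AP2/ERF factor and 6.82 for the zinc finger protein. It was -10.55 for the S-locus-specific glycoprotein, -6.07 for the Kunitz-type protease inhibitor, -5.82 for serine-pyruvate aminotransferase, -5.31 for Dhn1 and -5.22 for CBP20. In all, 105 genes were higher in leaf and lower in tuber, where independent lists would share 95.3, and 63 were lower in leaf and higher in tuber, where they would share 94.1. The numbers for independent lists take every measured gene as equally likely to be called.

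The zinc finger, AP2/ERF, calcium pump, phosphatase and CYP707A1 genes that were lowest under red light in tubers had a median log2 ratio of -4.60 over 6 genes. Paired counting of reads acting through gene length is argued against by the size of the trend. The median log2 ratio of all genes per bin of exon length ran only from -0.20 to 0.20 over 20 bins. With that trend removed the median of the 6 genes was -4.69 (-4.10 to -5.31), which so small a trend could not have brought within 2-fold. Wounding or handling of the dark tubers at harvest may contribute, and the rule set beforehand was met by a narrow margin. The 115 WRKY and calmodulin genes, leaving out the named ones, had a median of -0.11 (percentile 1.93) against a bound of -0.10 for random lists. Of these, 16 were lower, 3 higher and 96 neither. Other wound-associated values were added after the result and do not decide the question. Wound-inducible CBP20, named for its opposite ratios, was 15.9-fold higher under red light (14.3 to 17.7). Protease inhibitors had a median of 0.66 (percentile 100) with 14 higher and 4 lower. The jasmonate list (median 0.36, percentile 96.6) and the defence list (median -0.07, percentile 6.2, 26 higher and 6 lower) were within random lists. A difference in time of day cannot be told apart from light, because no label gives the harvest time. The clock list had a median of 0.085 (percentile 64.6, 31 genes), but a median over members that went both ways cannot decide this. A response to red light, which the design names, stays open and untested.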

How the results depend on the processing

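Alternatives chosen only after the data were seen were the deposited counts, all counts divided by 2 and lists without accidental members. No paired analysis was possible because the groups share fewer than 2 replicate numbers, with 1 library per group; leaving out a replicate was not run for the same reason, nor was the alternative for a normalized unit, since the files hold counts, and a fit of light with tissue as a block was not run. Of the counts and the leaf-tuber relation, 86 values under alternatives fixed beforehand and 20 under added ones were kept, and 16 moved. A count was kept where it stayed within 1.5 times its main value. For the relation, Pearson's r stayed close, at 0.321 against a Spearman correlation of 0.317. A ratio beyond 2-fold without its interval, a looser rule, gave 2074 lower genes in leaf light, 2734 higher and 1723 lower in tuber light, 1462 genes of the same and 406 of opposite direction in both tissues. An interval beyond 4-fold, a stricter rule, gave 968 higher and 108 lower in leaf light, 681 and 240 in tuber light, 1559 and 1255 for dark leaf against dark tuber, 1860 and 1235 for red light leaf against red light tuber, and 196 and 16 genes of the same and of opposite direction. With a mean of at least 10 CPM the Spearman correlation was 0.374. Of the list medians, 1827 values under alternatives fixed beforehand kept their call, 32 came to stand apart from random lists and 53 no longer did. Another 8 are called reversed, though no list moved from above random lists to below them or back. Storage, glycoalkaloid, gibberellin and pollen fell within random lists with a median of opposite sign. Cytokinin and abscisic acid, darkness and starvation, and cytosolic ribosome came to stand apart on the side opposite their main percentile. Under the added alternative 39 kept their call, 3 came to stand apart and 2 no longer did. A change of scaling moves a list and its random lists together, so calls could change there only through the pseudocount, the filter or the matching. Kept calls under those settings therefore say little. The changed calls follow by setting, with dark tissues for dark leaf against dark tuber and lit tissues for red light leaf against red light tuber. Their cause was not tested unless stated. DESeq2 size factors put apart, in leaf light lignin 0.47. TMM from the pair put apart, in leaf light lignin 0.49, and ended calls, in leaf light reference genes 0.15. Library totals put apart, in leaf light lignin 0.54, and ended calls, in leaf light reference genes 0.20, in dark tissues phenylpropanoid -0.15, heat shock 0.45, and reversed calls in lit tissues storage 0.29. Upper-quartile factors put apart, in leaf light lignin 0.40, cytokinin and abscisic acid 0.39, and ended calls, in dark tissues carotenoid 0.46. Leaving out the 20 highest genes put apart, in leaf light lignin 0.56, and ended calls, in leaf light reference genes 0.19, in dark tissues phenylpropanoid -0.28, in lit tissues storage -0.39. Thinning put apart, in dark tissues reference genes -0.46, and ended calls, in leaf light gibberellin 0.39, reference genes 0.12, in dark tissues phenylpropanoid -0.35. No filter put apart, in leaf light lignin 0.44, in tuber light root 0.27, in dark tissues auxin 0.13, miRNA-target factors 0.18, and ended calls, in leaf light darkness and starvation -0.20, defence 0.0047, reference genes 0.036, in tuber light chlorophyll breakdown 0.20, glycoalkaloid 0.021, in dark tissues carotenoid 0.16, sucrose 0.22, storage -0.44, protease inhibitors -0.24, heat shock 0.14, root 0.27, in lit tissues photorespiration 0.54, suberin -0.13, storage -0.34, nitrate 0.23, root 0.23. A filter of 5 CPM put apart, in leaf light carotenoid 0.45, phenylpropanoid 0.39, other miRNA targets -0.50, in tuber light cytosolic ribosome 0.10, in dark tissues starch -0.55, reference genes -0.74, in lit tissues cytokinin and abscisic acid 0.44, and ended calls, in leaf light glycoalkaloid 0.38, defence -0.21, gibberellin 0.028, in tuber light chlorophyll breakdown 0.35, in dark tissues heat shock 0.20, cell cycle -0.20, in lit tissues jasmonate 0.35, nitrate 0.081, and reversed calls in dark tissues cytokinin and abscisic acid -0.47, pollen 0.74. Members of at least 10 CPM put apart, in leaf light carotenoid 0.54, miRNA-target factors 0.057, in tuber light nitrate 0.52, cytosolic ribosome 0.11, in dark tissues starch -0.61, reference genes -0.75, in lit tissues heat shock -0.32, and ended calls, in leaf light flavonoid 0.092, defence -0.16, in tuber light chlorophyll breakdown -0.035, glycoalkaloid 0.99, in dark tissues heat shock 0.14, cell cycle -0.10, in lit tissues chlorophyll breakdown 0.73, jasmonate 0.35, nitrate 0.25, root 0.35, and reversed calls in leaf light glycoalkaloid -0.79, gibberellin -0.26, in tuber light darkness and starvation 0.54, in dark tissues pollen 0.67. A pseudocount of 0.1 put apart, in leaf light cytokinin and abscisic acid 0.42, and ended calls, in dark tissues carotenoid 0.66. A pseudocount of 2 put apart, in leaf light lignin 0.37, and ended calls, in tuber light chlorophyll breakdown 0.32, in dark tissues phenylpropanoid -0.28. Unmatched random lists, which move only the percentile, put apart, in leaf light lignin 0.44, cytokinin and abscisic acid 0.37, heat shock -0.24, in dark tissues reference genes -0.39, in lit tissues heat shock -0.24, and ended calls, in leaf light defence -0.18, reference genes 0.14, in dark tissues heat shock 0.20, in lit tissues photorespiration 0.81, chlorophyll synthesis 0.36, and reversed calls in lit tissues cytosolic ribosome -0.22. Leaving out accidental members put apart, in dark tissues plastid isoprenoid 1.08, glycoalkaloid -2.05, miRNA-target factors 0.25, and ended calls, in tuber light glycoalkaloid 0.99, in lit tissues photorespiration 0.86. The glycoalkaloid reversal in leaf comes from the SGT1 genes, the abundant members. Of the named genes, 641 values were the same under DESeq2 size factors or library totals, 4 passed and 3 lost 2-fold, and 0 reversed.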

Other observations

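In this part the test on leaf-abundant genes and the test on scaling were chosen after the results were seen, and the tests on gene length and meristem markers before. Sugar and cell wall genes of the tuber libraries went both ways. Sucrose metabolism and sugar transport had 5 of 78 genes higher and 2 lower (median 0.37, percentile 100), with vacuolar invertase (PGSC0003DMG400013856), which splits sucrose, 6.88-fold higher (5.97 to 7.96), the Kunitz-type tuber invertase inhibitor (PGSC0003DMG400010146) at a ratio of 1.96 (1.94 to 1.98) and the tuber-specific sucrose-responsive element binding factor (PGSC0003DMG400007994) 10.6-fold lower (6.82 to 17.0). Cell wall genes had 31 of 167 higher and 21 lower (median 0.20, percentile 98.9), with a pair of extensins, structural wall proteins, 229-fold (134 to 430, PGSC0003DMG400000794) and 6.20-fold higher (5.94 to 6.48, PGSC0003DMG400000776) and the wall-loosening XTH3 (PGSC0003DMG400014823) 10.7-fold lower (9.08 to 12.7). Oxidative stress genes had 39 of 112 higher and 1 lower (median 0.81, percentile 100), with a thioredoxin (PGSC0003DMG400003449) 13.6-fold higher (8.81 to 22.2), catalase (PGSC0003DMG400029408), at 7648 CPM, at a ratio of 1.01 (1.00 to 1.02) and thioredoxin h (PGSC0003DMG400021716) 2.44-fold lower (2.35 to 2.53). Auxin genes lay below random lists (median -0.21, percentile 0.190, 4 of 103 higher and 13 lower), with an auxin-regulated kinase (PGSC0003DMG400004860) 7.63-fold lower (6.92 to 8.42), an auxin growth promotor protein (PGSC0003DMG400016201) at 1.33 toward darkness (1.29 to 1.37) and the auxin-conjugating enzyme GH3.5 (PGSC0003DMG400021676) 9.08-fold higher (7.05 to 11.9).

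Heat shock and chaperone genes took 5.90% of the reads in dark leaf, 4.85% in red light leaf, 5.82% in dark tuber and 5.02% in red light tuber. In tubers 36 of 192 were higher under red light and 5 lower (median 0.09, percentile 89.3; -0.09 under upper-quartile scaling), and in leaves 13 of 190 were higher and 27 lower (median -0.24, percentile 3.69), neither list standing apart, although the leaf list was below unmatched random lists (percentile 0.18). The heat shock protein Hsp20.1 (PGSC0003DMG400017098) was 16.7-fold higher in red light tubers (11.4 to 25.5), heat shock cognate 80 (PGSC0003DMG400022159) had a ratio of 1.61 toward darkness (1.60 to 1.62) and an hsp70 (PGSC0003DMG400011197) was 5.58-fold lower (4.73 to 6.59). In leaves a small heat shock protein (PGSC0003DMG400002928) was 10.1-fold higher (8.11 to 12.7), a DnaJ gene (PGSC0003DMG400003565) 5.30-fold lower (4.92 to 5.71) and heat shock protein 70 (PGSC0003DMG400008917) at a ratio of 1.12 toward darkness (1.11 to 1.13). Clock genes in tubers had 8 of 31 higher and 1 lower (median 0.08), and a pair of ELF4-type genes went in opposite directions, EARLY flowering 4 (PGSC0003DMG400001221) at least 448-fold higher and ELF4 (PGSC0003DMG400030357) 3.27-fold lower (3.14 to 3.41), with CONSTANS interacting protein 2b (PGSC0003DMG400008989) at a ratio of 1.88 toward darkness (1.83 to 1.93).

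Photosynthesis genes were much higher in the red light tuber library, and leaf or shoot tissue mixed into that sample could give the same picture. Against this, 68 genes abundant in red light leaf and near absent from dark tuber, outside the fixed photosynthesis lists, stood at a median of 6.39% of their leaf level in red light tuber (quartiles 0.405 and 39.6), while 22 light-harvesting genes stood at 101% (quartiles 60.9 and 189). The spread was wide: carbonic anhydrase reached 1.08% of its leaf level, 24K germin 0.160% and aquaporin TIP2 0.296%, but serine hydroxymethyltransferase 86.8%, a pair of CP29 genes 80.6% and 55.1%, a chloroplast ATP synthase chain 46.6% and phospholipase D delta 40.6%. The set thus still holds photosynthesis genes that the lists' words missed, yet 36 of the 68 stayed under 10%, which argues against leaf tissue as the whole source and leaves a small share of it open. Paired counting acting through gene length is argued against too, since the length trend of all genes ran only from -0.20 to 0.20 over 20 bins. The light-harvesting median was 6.49 after this trend was removed and 6.61 before. That lit peel turns on these genes itself remains a hypothesis.

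Cell cycle genes were higher in the red light leaf library, with a median of 1.71. The 4 other scalings shifted the median of all leaf genes by only -0.05 to 0.07, and the list median lay between 1.63 and 1.78 under them. Shifts of that size could not have removed the ratio, so it does not come from the choice among these scalings. An error common to all scalings was not tested. The 27 genes matched by words for meristem and young organ markers had a median of 0.55, above random lists (percentile 99.6, upper bound 0.36). This lay well under the cell cycle median, with 7 higher, 2 lower and 18 neither. Many of the 27 are described only as receptor protein kinase CLAVATA1, and the words do not show that each gene marks the meristem. More shoot apex or very young leaf in that sample therefore cannot be told apart from a light response. Both explanations may hold in part, and the labels do not say which leaves were taken. By the labels, the red light leaves had the same dark period as the dark leaves and then the light. They would thus have been older at harvest, and no dark leaf library covers those later times. Plant age and time of harvest therefore cannot be told apart from light in any leaf light ratio, and their part was not tested.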
